A study of Mus musculus with 8 samples.

How the data were processed

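Mouse NK cells from T-cell-depleted bone marrow were measured on 8 Affymetrix Mouse Gene 2.0 ST arrays in 4 groups of 2 biological replicates: fresh cells (day 0), cells after 4 days or 9 days with 1000 IU/mL of IL-2, and 9-day cells with KU55933 (7.5 µM, added on day 4). Activated cells were collected by adherence, and RNA was amplified once and labelled with biotin. Samples were grouped by their labels alone. The labels do not say whether day 9 cells without inhibitor received vehicle, and no batch information was used here.

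Per the submitters' processing notes, the array signals were summarized by RMA, and the deposited values are log2 signals per transcript cluster (41345 clusters on 8 arrays). A second deposited table gives, for 11036 clusters, the authors' average log2 signal per group together with an ANOVA p-value and a false discovery rate p-value over all conditions from the Transcriptome Analysis Console. Its averages lay within 0.005 of the means of the 2 arrays, its highest false discovery rate p-value was 0.0998, and 8619 of its clusters lay below 0.05. It lists 7752 of the 13998 genes tested here, and it was used only as an alternative. Versions of the authors' tools and the genome build of the array annotation are not given in the sources used here.

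Gene symbols came from the supplied table of the array's probes: 23521 clusters named 1 symbol, 1820 named several and 16004 listed none. A symbol table of mouse RefSeq genes held 23328 of the single-symbol names and lacked 193, and no symbol was changed. Each of 22180 genes was represented by its brightest cluster, which mattered for 1082 genes with several. Genes were tested if they reached the array median (percentile 50 of all clusters) on at least 2 arrays, leaving 13998. Clusters naming no gene or several were left out of the gene tests, and the genes they hold were not analysed here.

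Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom and 3.69 from the prior), and 5 comparisons were made: day 4 and day 9 each against day 0, day 9 against day 4, and KU55933 at day 9 against day 9 and against day 4. The day 0, day 4 and day 9 arrays enter more than one comparison, so comparisons that share a group are not independent. The covariance of 2 of them was checked against 100 simulated data sets in which all groups had the same mean, without an effect of day or inhibitor. P-values were adjusted by Benjamini-Hochberg within a comparison and called below 0.05. Array centring, as an alternative, subtracted each array's median over the tested genes. The share of genes whose 2 groups do not overlap has a chance value of 33.3%.

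The 25 gene lists and 12 marker lists of other cell types, the comparisons and the alternatives in the first table of choices were written before the data were examined. Lists were tested with limma's camera (preset correlation 0.01) and adjusted over the 37 lists of a comparison. They were tested again with the correlation estimated from the arrays, which with 2 arrays per group is estimated from 4 residual degrees of freedom, and with limma's fry. Of the genes on the lists 633 were tested, 39 lay below the filter and 78 had no cluster naming them alone. Genes were named by a rule: the 8 largest changes each way among called genes whose arrays did not overlap, leaving out predicted, antigen receptor and small RNA genes; the 4 called members with the lowest adjusted p of each list with at least 3 called; and fixed genes of NK cell function and of the DNA damage response. Genes named outside it are marked in the text, apart from members of the marker lists and of lists with fewer called members, which were also chosen after the values were seen.

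The code was tested on simulated data with 200 changed genes among 13998 in 20 runs. For day 4 against day 0 it recovered 24.2% of 1.5-fold, 87.1% of 2-fold and 100% of 4-fold changes with 4.07% false calls. For KU55933 against day 9 it recovered 26.0%, 88.7% and 99.6% with 4.56% false calls. Camera called a changed list (unadjusted p below 0.05) in 20 of 20 runs, and an unchanged list in 0 runs of the first and 1 of the second. The noise was drawn independently for each gene, so these runs cannot test camera's preset correlation. In the data 59.9% of genes changed for day 4 against day 0, so the recovery rates do not carry over to that comparison.

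The alternatives, whose effect the closing section gives, were no dim filter, a filter at percentile 75, every cluster tested, the mean of a gene's clusters, centring, quantile normalization, a mean-variance trend, robust fitting, array weights, replicate number as a block, each array left out in turn, only the 4 arrays compared, a 2-fold minimum with and without adjustment, a minimum of 1.2-fold tested by limma's treat, the authors' averages, and the list tests named above. Leaving out the day 0 arrays was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.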

Results

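Gene expression of mouse natural killer (NK) cells was measured on 8 Affymetrix Mouse Gene 2.0 ST arrays. The cells came from bone marrow depleted of T cells, and 4 groups of 2 biological replicates were compared. Day 0 cells were freshly isolated. Day 4 cells had been activated with 1000 IU/mL of interleukin-2 (IL-2), called acute activation. Day 9 cells had received IL-2 again on day 4, called chronic activation. The last group was day 9 cells given KU55933 at 7.5 µM from day 4. KU55933 inhibits ATM, a kinase that signals DNA double-strand breaks. The protocol mentions a vehicle, and the labels do not say whether the day 9 arrays without inhibitor received it.

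Array medians lay between 3.66 and 3.91 on the log2 scale, and 13998 genes were bright enough to be tested. The first principal component (68.3% of the variance) separated fresh from activated cells and the second (22.9%) separated day 4 from day 9. Across genes, which are not independent replicates, the 2 arrays of a group correlated at 0.971 on day 0, 0.991 on day 4, 0.981 on day 9 and 0.986 with KU55933. Day 9 replicate 2 correlated more highly with a KU55933 array (0.986) than with its own replicate. The SD between replicates was 0.27, 0.14, 0.19 and 0.16 for the 4 groups, so the fresh cells were the most variable, and 2 arrays per group limit the precision of every value. Changes are log2 differences as deposited, ± is the standard error from limma, and adjusted p-values are limma's after Benjamini-Hochberg adjustment, called below 0.05. Lists of genes were written before the data were examined and tested with limma's camera, adjusted over the 37 lists of a comparison. The granzymes Gzmc to Gzmg, the Klra receptors, Try4 and Try5, the H2 genes and Mt1 and Mt2 have near-identical relatives, so which copy their probes read is uncertain. Signal below the array median was treated as background, so a change and its fold are lower bounds where one group lay there. Among the genes given below this holds at least for Gzmc, Gzmd, Gzmf, Gzmg, Dsc1 and Dsc2 against day 0 and for the fall of Ppbp. It also holds for Fam171b and Dsg2 against day 4, and for the falls of Chil3, Igsf6 and S100a8 from day 4. The falls of Slamf6 to day 9 are such bounds too, and Ifi204 and Oasl2 lay below the median on day 9.

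After acute activation the transcripts of division, cytotoxic granules and biosynthesis stood far above those of fresh NK cells. By day 4 genes of granule proteases, of the mitotic and replication machinery and of the sterol and glycolytic enzymes were higher than on day 0, while immediate-early transcripts were lower. None of these list calls held with camera's correlation estimated (lowest adjusted p = 0.0789 with an estimated correlation). Gzmd (transcript cluster 17306991), a granule serine protease, rose by 9.61 ± 0.14 (781-fold, adjusted p = 7.12e-08). Bub1 (17391376), a mitotic checkpoint kinase, rose by 4.45 ± 0.11 (21.9-fold, adjusted p = 6.17e-07), and the sterol demethylase Cyp51 (17445308) by 4.73 ± 0.11 (26.5-fold, adjusted p = 6.17e-07). Fos (17277387), an immediate-early transcription factor, fell by 5.56 ± 0.15 (47.2-fold, adjusted p = 6.17e-07). In all, 8391 of 13998 genes (59.9%) changed, 5250 upward and 3141 downward, and 4045 of them changed at least 2-fold. The arrays of the 2 days did not overlap for 78.6% of genes, against 33.3% by chance. Centring each array on its own median shifted every change by -0.35. It then called 9620 genes, 40.4% of them upward against 62.6% as deposited, and 7026 genes were called in the same direction both ways. For 78 genes called as deposited the change had the other sign after centring, whether or not it was then called. None of the named genes past the threshold changed sign. Each list median shifts with centring by the same amount in a comparison, and centred medians follow for the main lists.

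Genes of division, recombination and checkpoint signalling rose on day 4. All 29 tested genes of G2/M and mitosis rose (median 3.12, centred 2.77, camera adjusted p = 6.55e-13, adjusted p = 0.0852 with an estimated correlation), among them Plk1 (3.79), Cenpe (3.7), Kif11 (3.69) and Mki67 (2.35). Among the 31 tested genes of G1/S and DNA replication 30 rose (median 2.33, centred 1.98, camera adjusted p = 1.8e-10, adjusted p = 0.0935 with an estimated correlation), among them Rrm1 (3.44) and Prim1 (3.22). Repair by homologous recombination and the Fanconi pathway gained 22 of 23 genes (median 2.02, centred 1.67, camera adjusted p = 2.31e-06, adjusted p = 0.0852 with an estimated correlation), with Fancd2 at 3.02 and Brca1 at 2.39. Of the 27 tested genes of ATM and ATR signalling 23 rose and none fell (median 1.30, centred 0.95, camera adjusted p = 1.35e-05, adjusted p = 0.0852 with an estimated correlation). The checkpoint kinases Chek1 (2.82) and Chek2 (1.46) were among them, whereas Atm itself did not change (0.05, adjusted p = 0.787). End joining (median 0.57, centred 0.22, camera adjusted p = 0.0602) and base, nucleotide and mismatch repair (median 0.54, centred 0.19, camera adjusted p = 0.0902) did not pass as lists, although Xrcc5 (2.25) and Ddb1 (1.91) rose. Of the 23 base repair genes 9 rose and 8 fell after centring.

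The p53 targets split on day 4, 14 rising and 10 falling of 28 (median 0.35, centred 0.00, camera adjusted p = 0.905). Cdkn1a (17335467), the cyclin-dependent kinase inhibitor p21, rose by 2.41 (5.33-fold, adjusted p = 1.66e-06), Ccng1 by 2.61 and Mdm2 (17245248) by 1.09, while Btg2 fell by 2.78. The cell cycle inhibitor and senescence list had a median of 0.03 as deposited and -0.32 after centring (camera adjusted p = 0.713), with a rise of Cdkn2c (2.38). The apoptosis list also changed sign with centring, from 0.06 to -0.28 (camera adjusted p = 0.59), with a fall of Pmaip1 (-3.16) and a rise of Casp8 (1.96).

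Biosynthetic metabolism rose at day 4 as well. All 23 tested genes of cholesterol and fatty acid synthesis were higher (median 3.06, centred 2.71, camera adjusted p = 1.8e-10, adjusted p = 0.0789 with an estimated correlation), including Fads2 (4.55), Hmgcs1 (4.35) and Sqle (3.96). Glycolysis gained 16 of 18 genes (median 1.75, centred 1.41, camera adjusted p = 3.3e-05, adjusted p = 0.0852 with an estimated correlation), such as the lactate carrier Slc16a1 (3.95) and Pgk1 (2.74). Oxidative phosphorylation gained 22 of 28 (median 1.05, centred 0.70, camera adjusted p = 0.000157, adjusted p = 0.188 with an estimated correlation), with Sdhd at 1.99. Amino acid supply and the integrated stress response gained 15 of 20 (median 1.74, centred 1.39, camera adjusted p = 0.00157, adjusted p = 0.108 with an estimated correlation), with Slc7a5 at 4.41 and Shmt2 at 3.59. Its stress factors Ddit3 (-2.55) and Nupr1 (-1.57) fell, a pair singled out after the values were seen. The unfolded protein response (median 1.30, centred 0.96, camera adjusted p = 0.0544) and the oxidative stress response (median 0.45, centred 0.10, camera adjusted p = 0.2) did not pass as lists, though Sdf2l1 (2.31) and Mt2 (3.29) rose and Hmox1 (-2.22) fell.

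The cytotoxic machinery was raised while receptors and cytokines were reshuffled. Of the 23 tested granule and death-ligand genes 16 rose (median 1.30, centred 0.95, camera adjusted p = 0.00047, adjusted p = 0.0852 with an estimated correlation), with Gzmc (8.61), Gzmb (2.97, 7.84-fold) and Prf1 (2.35, 5.11-fold). Genes of IL-2 and STAT5 signalling rose in 14 of 20 cases (median 0.90, centred 0.56, camera adjusted p = 0.0466, adjusted p = 0.202 with an estimated correlation). Without either day 9 array that list just missed (adjusted p = 0.0512), and quantile normalization left it uncalled (adjusted p = 0.263). The IL-2 receptor alpha chain Il2ra rose by 3.66 (12.7-fold, adjusted p = 6.64e-07), Il2rb by 1.37 and Cish by 1.83. Chemokine receptor and trafficking genes fell in 9 of 17 cases (median -0.48, centred -0.82, camera adjusted p = 0.00648, adjusted p = 0.108 with an estimated correlation), Cxcr4 (-3.74) and Ccr7 (-2.56) among them. NK receptors and adaptors did not pass (median -0.09, mean 0.01, centred -0.44, camera adjusted p = 0.293), with 11 rising and 13 falling of 30 as deposited and 8 rising and 16 falling after centring. Klra5 (4.58) and Klrg1 (2.93) rose, Itga2 (-2.19) fell, and Ncr1 (0.21, adjusted p = 0.122) and Klrk1 (-0.28, adjusted p = 0.0562) did not pass. Inhibitory and exhaustion genes split evenly, 10 up and 10 down of 25, and their median went from 0.01 to -0.33 on centring (camera adjusted p = 0.661). Havcr2 (17248809), which encodes TIM-3, rose by 4.40 (21.1-fold, adjusted p = 1.02e-06) and Tigit by 3.57, while Pdcd1 fell by 0.47. NK transcription factors (median -0.35, centred -0.70, camera adjusted p = 0.0902), the TNF receptor family (median 0.45, centred 0.11, camera adjusted p = 0.0851) and cytokines and chemokines did not pass as lists. The cytokine median changed sign with centring, from 0.14 to -0.20 (camera adjusted p = 0.55). Eomes (1.06), Zbtb32 (3.33), Tnfrsf9 (4.47) and Tgfb1 (1.03) rose, and Tbx21 (-0.93), Ccl5 (-1.69) and Ifng fell. The fall of Ifng (-0.48, adjusted p = 0.0477) was lost without day 0 replicate 2 (0.19), day 4 replicate 1 (0.172), day 4 replicate 2 (0.117) or either day 9 array (0.0628).

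Immediate-early genes fell at day 4 in 19 of 22 cases (median -2.81, centred -3.15, camera adjusted p = 1.7e-10, adjusted p = 0.108 with an estimated correlation), including Nr4a1 (-5.05) and Zfp36 (-3.41). These genes are often raised by tissue dissociation. Interferon-stimulated genes did not pass (median -0.29, centred -0.63, camera adjusted p = 0.27), 7 rising and 8 falling of 24 as deposited and 5 rising and 12 falling after centring, with Irf7 at -2.10 and Igtp at 1.24. Markers of other blood cells moved as well. Neutrophil genes rose in 12 of 15 cases (median 1.75, centred 1.40, camera adjusted p = 0.00197, adjusted p = 0.0935 with an estimated correlation). B cell genes fell in 10 of 11 cases (median -1.54, centred -1.88, camera adjusted p = 1.97e-05, adjusted p = 0.136 with an estimated correlation), and all 11 dendritic cell genes fell (median -1.75, centred -2.10, camera adjusted p = 3.25e-06, adjusted p = 0.0852 with an estimated correlation). All 5 megakaryocyte genes fell, Pf4, Ppbp, Itga2b, Gp9 and Treml1 (median -3.35, centred -3.69, camera adjusted p = 0.000157, adjusted p = 0.11 with an estimated correlation). Macrophage genes split, 7 up and 9 down of 18 (median -0.27, mean 0.19, centred -0.61, camera adjusted p = 0.33), with Chil3 (4.51) up and Csf1r (-1.52) down. Not called were mast cell and basophil (median -0.35, centred -0.69, adjusted p = 0.191), eosinophil (-0.28, 0.518), erythroid (-0.72, 0.2), T cell (-0.76, 0.0969), innate lymphoid (-0.17, 0.315), stem and progenitor (-0.63, 0.0544) and stromal and endothelial genes (-0.31, 0.295). Adjusted over the list alone, the counts given for this comparison were the same except for NK receptors (14 fell), inhibitory genes (11 rose), neutrophil genes (13 rose) and B cell genes (11 fell).

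No list reached significance in this comparison when the correlation between its genes was estimated from the arrays (lowest adjusted p = 0.0789), and limma's fry called 31 lists. Of the 115 named genes past the threshold 114 stayed past it whichever array was left out, and all 115 kept their sign.

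**Figure D1:**
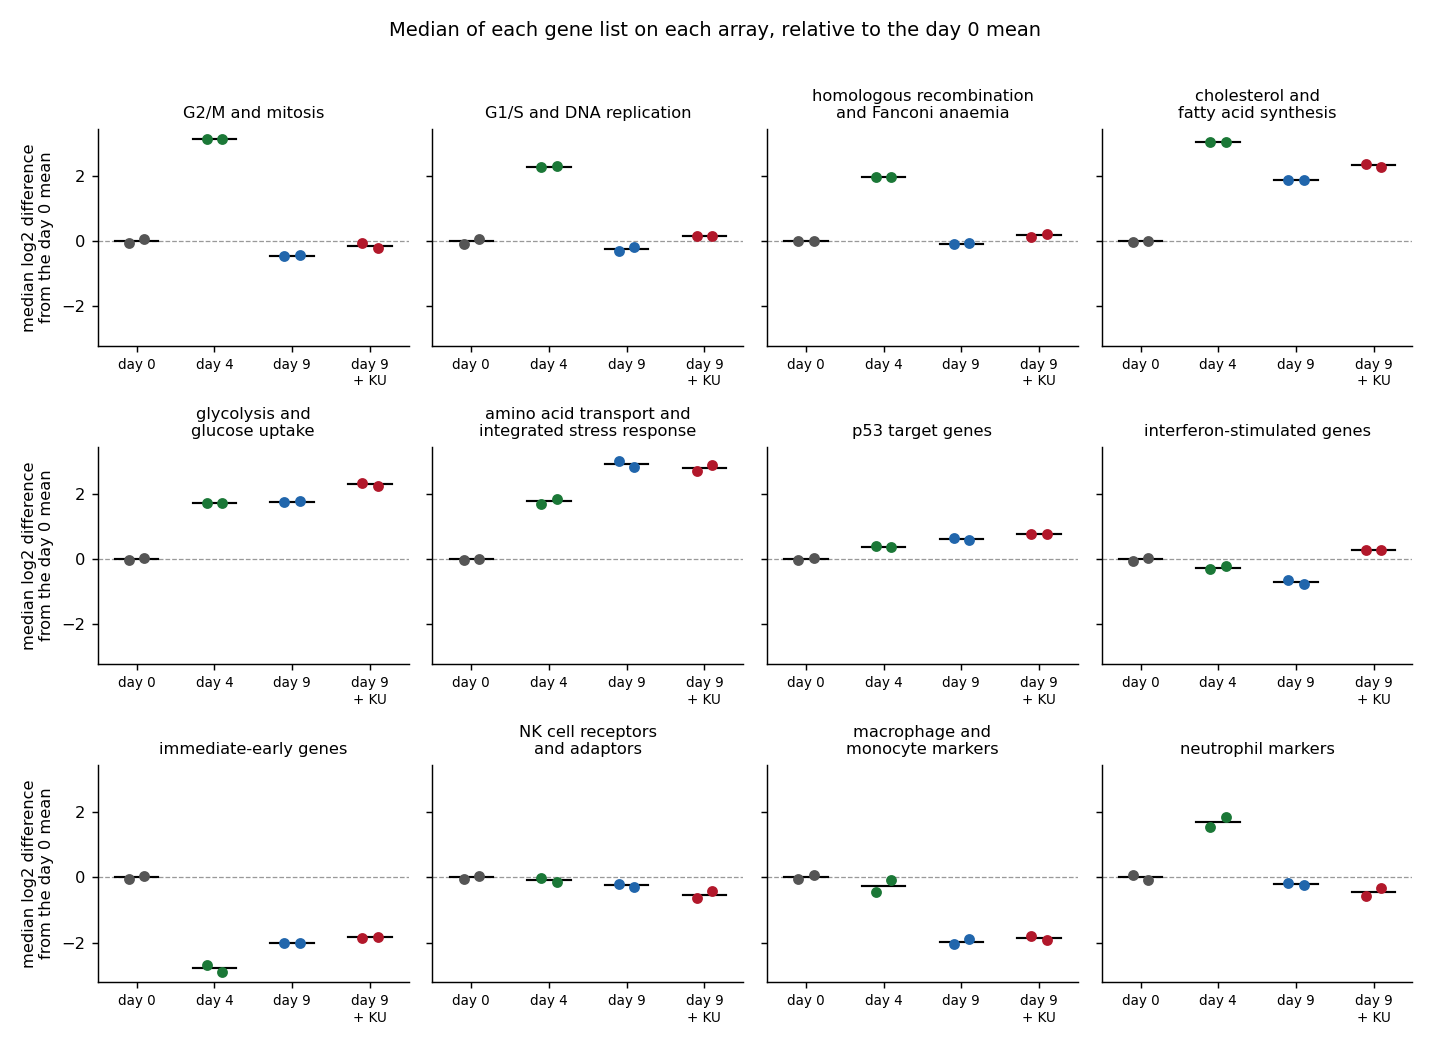
Median log2 difference from the day 0 mean over the tested genes of 12 lists, 1 panel per list; the horizontal axis gives the 4 groups, each point is an array and each bar is the mean of the 2 arrays of a group.

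After chronic activation granule and metabolic genes were still above fresh cells, and the rise of the division genes was largely gone. On day 9 the proteases, Havcr2, the p53 target Cdkn1a and amino acid transporters stood far above fresh cells, whereas interferon-stimulated genes stood below them and mitotic genes were no longer raised. As on day 4, none of the list calls held with camera's correlation estimated (lowest adjusted p = 0.0797 with an estimated correlation, 0.177 for interferon-stimulated genes). Gzmd rose by 9.98 (1011-fold, adjusted p = 5.32e-08), Gzmg by 9.66 (809-fold) and Gzmf by 9.58 (766-fold). Havcr2 rose by 5.63 ± 0.15 (49.6-fold, adjusted p = 3.54e-07), Cdkn1a by 3.86 ± 0.10 (14.5-fold, adjusted p = 3.54e-07) and the desmosomal cadherin Dsc2 by 6.69 ± 0.13 (103-fold, adjusted p = 1.58e-07). The largest fall was that of the platelet chemokine Ppbp (-7.19, 146-fold), and Fos fell by 6.15 (71.1-fold). In all, 8112 of 13998 genes (58.0%) changed, 5033 upward and 3079 downward, 3843 of them at least 2-fold. The arrays did not overlap for 75.7% of genes, against 33.3% by chance. Centring shifted changes by -0.23 and called 8718 genes, 46.8% upward against 62.0% as deposited, 7157 of them called in the same direction both ways.

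Amino acid supply and the integrated stress response was the most uniformly raised list on day 9, with 19 of 20 genes up (median 2.93, centred 2.70, camera adjusted p = 3.16e-08, adjusted p = 0.0797 with an estimated correlation), Slc7a5 (4.93) and Sesn2 (3.23) among them. Cholesterol and fatty acid synthesis gained 21 of 23 genes (median 1.87, centred 1.64, camera adjusted p = 8.37e-08, adjusted p = 0.0797 with an estimated correlation) and glycolysis 14 of 18 (median 1.76, centred 1.53, camera adjusted p = 0.00027, adjusted p = 0.0961 with an estimated correlation). Oxidative phosphorylation rose in 20 of 28 cases (median 0.65, centred 0.42, camera adjusted p = 0.00904, adjusted p = 0.319 with an estimated correlation). The unfolded protein response rose in 14 of 19 (median 0.88, centred 0.66, camera adjusted p = 0.0165, adjusted p = 0.311 with an estimated correlation). Quantile normalization left neither of these last lists called (adjusted p = 0.0997 for each). Mt2 rose by 5.01 and Sqstm1 by 2.31, while the oxidative stress list as a whole did not pass (camera adjusted p = 0.508).

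Division genes were mostly at or below the level of fresh cells by day 9. No gene of the 29 for G2/M and mitosis rose and 16 fell (median -0.46, centred -0.69, camera adjusted p = 7.9e-05, adjusted p = 0.262 with an estimated correlation), Mki67 (17497334) by 1.51 (2.85-fold, adjusted p = 5.74e-05). G1/S and replication genes fell in 14 of 31 cases (median -0.22, centred -0.44, camera adjusted p = 0.0218, adjusted p = 0.375 with an estimated correlation), and that call was lost without day 0 replicate 2 (adjusted p = 0.0986). Homologous recombination (median -0.11, mean 0.05, centred -0.34, camera adjusted p = 0.555), ATM and ATR signalling (0.24, 0.84), end joining (0.52, 0.139) and base repair (0.29, 0.346) were not called. Atm did not pass (-0.36, adjusted p = 0.0796), while Xrcc5 (1.93) and Rad17 (1.53) rose and H2ax fell (-1.97). Of 28 p53 targets 16 rose and 6 fell (median 0.62, centred 0.39, camera adjusted p = 0.11), with Ccng1 at 3.59 (12-fold), Tnfrsf10b at 3.46 (11-fold) and Mdm2 at 2.60 (6.07-fold, adjusted p = 5.38e-06). The cell cycle inhibitor Cdkn2b rose by 2.43, and the list it belongs to did not pass (median -0.02, centred -0.25, camera adjusted p = 0.276).

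Cytotoxic and IL-2 response genes were above fresh cells. Cytotoxic genes rose in 17 of 23 cases (median 1.42, centred 1.2, camera adjusted p = 7.24e-05, adjusted p = 0.0797 with an estimated correlation), with Gzmb at 2.90 and Prf1 at 2.31. IL-2 and STAT5 genes rose in 15 of 20 (median 0.93, centred 0.70, camera adjusted p = 0.00761, adjusted p = 0.177 with an estimated correlation), Il2ra by 3.74 and Ccnd2 by 2.03. Trafficking genes fell in 11 of 17 (median -0.85, centred -1.08, camera adjusted p = 0.0038, adjusted p = 0.14 with an estimated correlation), Cxcr4 by 4.75. Inhibitory genes rose in 14 of 25 cases and fell in 7 without passing as a list (median 0.62, centred 0.39, camera adjusted p = 0.346), with Tigit (4.62) and Ctla4 (1.33) up and Pdcd1 (-0.44) down. NK receptors did not pass (median -0.24, mean 0.00, centred -0.47, camera adjusted p = 0.139), 10 up and 14 down of 30 as deposited and 8 up and 16 down after centring. Klrg1 rose by 3.76 and Slamf6 fell by at least 3.20. The small fall of Ncr1 (-0.39) was lost without day 9 replicate 1 (adjusted p = 0.0582) or replicate 2 (adjusted p = 0.0579). Cytokines (median -0.45, centred -0.68, camera adjusted p = 0.11) did not pass, though Ccl4 (-1.43), Ccl3 (-1.21) and Ifng (-1.33) fell.

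Interferon-stimulated genes fell in 16 of 24 cases on day 9 (median -0.74, centred -0.97, camera adjusted p = 0.000115, adjusted p = 0.177 with an estimated correlation), Irf7 by 2.64 and Oasl2 by 2.24. Immediate-early genes were lower than on day 0 in 19 of 22 cases (median -2.02, centred -2.25, camera adjusted p = 1.65e-09, adjusted p = 0.154 with an estimated correlation). Macrophage genes fell in 13 of 18 cases (median -1.97, centred -2.20, camera adjusted p = 3.24e-06, adjusted p = 0.262 with an estimated correlation), Lyz2 by 5.27. All 11 B cell genes fell (median -3.49, centred -3.72, camera adjusted p = 8.37e-08, adjusted p = 0.14 with an estimated correlation), as did 10 of 11 dendritic cell genes (median -2.58, centred -2.81, camera adjusted p = 1.03e-05, adjusted p = 0.0797 with an estimated correlation). The megakaryocyte genes fell again (median -4.57, centred -4.80, camera adjusted p = 7.75e-05, adjusted p = 0.152 with an estimated correlation). Adjusted over the list alone the counts printed for day 9 against day 0 were the same, apart from cytotoxic (18 rose), NK receptor (11 rose), interferon-stimulated (17 fell) and macrophage genes (15 fell). With an estimated correlation no list was called here either (lowest adjusted p = 0.0797), and fry called 33. Of the 118 named genes past the threshold 117 stayed past it whichever array was left out.

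**Figure D2:**
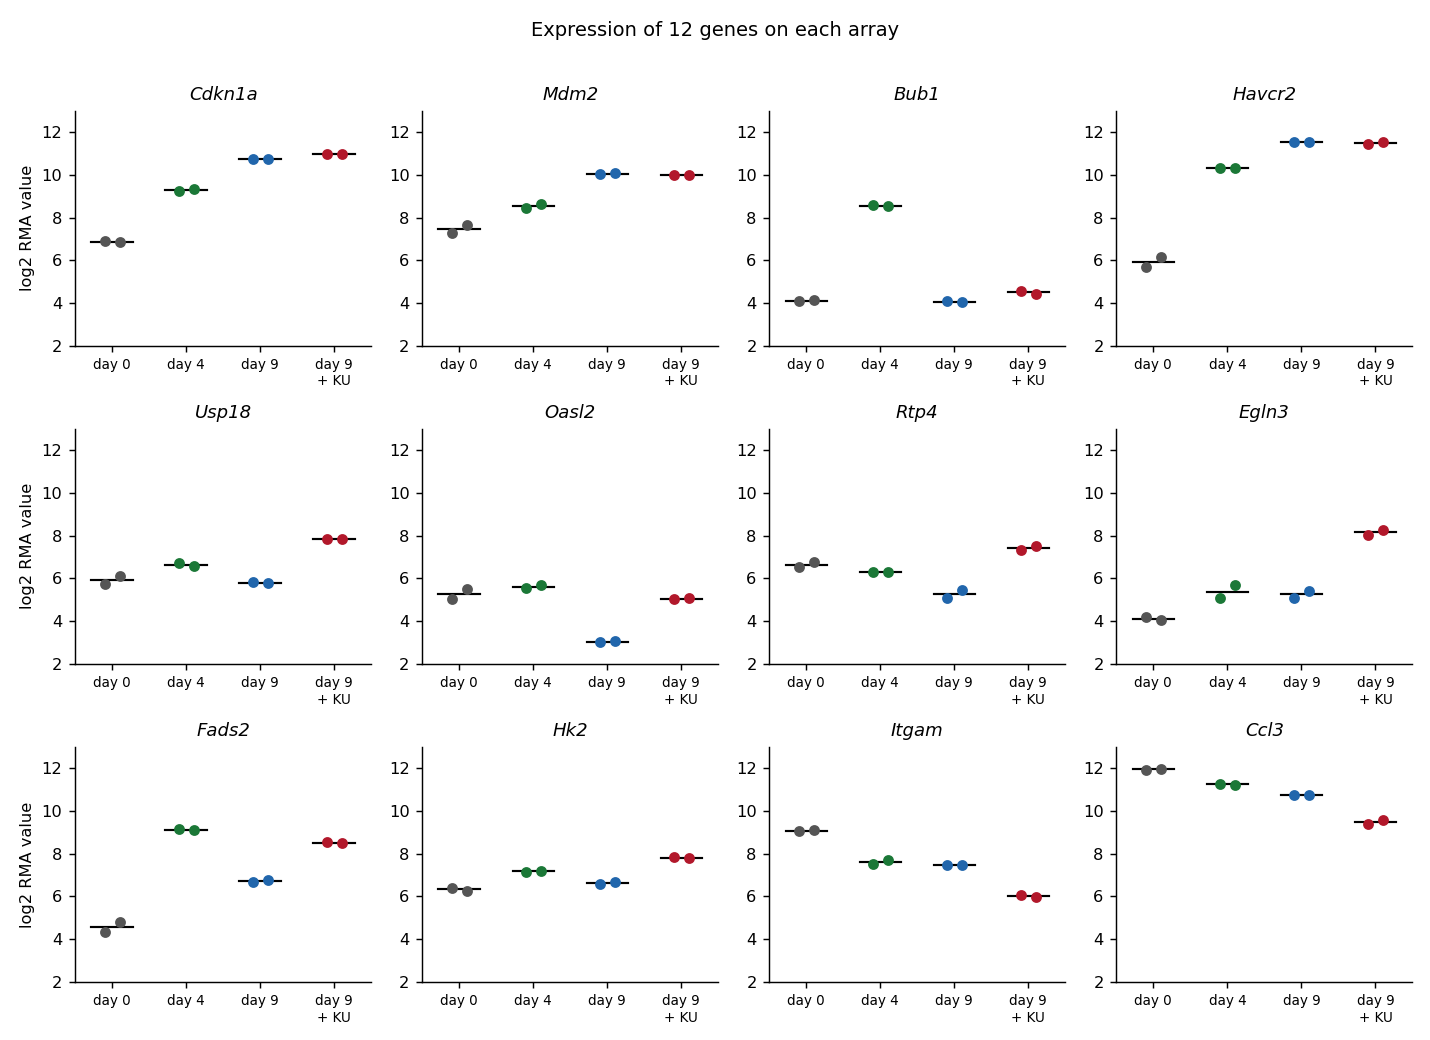
Log2 RMA values of 12 genes, 1 panel per gene; the horizontal axis gives the 4 groups, points are arrays and bars are group means.

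Between acute and chronic activation the division programme was lost. On day 9 mitotic, replication and recombination genes were far below day 4, p53 targets and stress-response genes were higher, and sterol and interferon-stimulated genes were lower. With an estimated correlation the p53 (adjusted p = 0.0513) and interferon calls (adjusted p = 0.222) were lost and the others held. Bub1 fell by 4.50 ± 0.11 (22.6-fold, adjusted p = 1.21e-06) and Mki67 by 3.86 (14.5-fold, adjusted p = 2.96e-06). Nupr1, a stress-induced transcriptional regulator, rose by 3.69 (12.9-fold, adjusted p = 2.42e-06), Cdkn1a by 1.45 (2.73-fold, adjusted p = 4.15e-05) and Mdm2 by 1.51 (2.85-fold, adjusted p = 0.000271). The largest rises were those of Fam171b (4.97 ± 0.21, 31.3-fold, adjusted p = 3.83e-06), the desmosomal cadherin Dsg2 (4.75), the glycosyltransferase B4galnt2 (4.58) and Ctsg (4.49), and the largest falls those of Chil3 (-4.91, 30.2-fold), Igsf6 (-4.75) and S100a8 (-4.73). A second transcript cluster of Dsg2 stayed below the array median, at 2.95 on day 4 and 3.07 on day 9. In all, 3898 of 13998 genes (27.8%) changed, 1710 upward and 2188 downward, 1240 of them at least 2-fold. The count was 2223 without day 4 replicate 1, 2241 without day 4 replicate 2 and 2374 without day 9 replicate 1. Arrays did not overlap for 67.9% of genes, against 33.3% by chance. Centring shifted changes by 0.12 and called 4179 genes, 58.9% upward against 43.9% as deposited, 3428 of them in the same direction both ways.

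Division, replication and recombination genes fell as groups. All 29 genes of G2/M and mitosis fell (median -3.51, centred -3.40, camera adjusted p = 2.83e-32, adjusted p = 0.0274 with an estimated correlation), including Ccna2 (-4.28), Kif11 (-4.18) and Plk1 (-4.14). All 31 genes of G1/S and replication fell too (median -2.31, centred -2.19, camera adjusted p = 1.75e-26, adjusted p = 0.0274 with an estimated correlation), among them E2f8 (-4.17), Mcm5 (-3.40) and Pole (-3.29). Homologous recombination and Fanconi genes fell in 20 of 23 cases (median -1.65, centred -1.54, camera adjusted p = 4.86e-12, adjusted p = 0.0274 with an estimated correlation), with Rad54l at -3.42, Fancd2 at -3.35 and Brca1 at -2.69. ATM and ATR signalling lost 18 of 27 genes and gained none (median -0.61, centred -0.49, camera adjusted p = 4.68e-09, adjusted p = 0.0274 with an estimated correlation), with Clspn (-3.69), H2ax (-3.06) and Chek1 (-2.56). Adjusted over the list alone 20 of these fell and 1 rose, and the other counts of this paragraph stayed the same. Atm was not called (-0.41, adjusted p = 0.0874). End joining (median -0.22, centred -0.11, camera adjusted p = 0.322) and base repair (median -0.12, centred -0.01, camera adjusted p = 0.322) did not pass.

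Targets of p53 rose in 13 of 28 cases while Fas (-0.50) and Ckap2 (-2.88) fell (median 0.53, centred 0.64, camera adjusted p = 4.5e-05, adjusted p = 0.0513 with an estimated correlation). Adjusted over the list alone 16 rose and 3 fell. Trp53inp1 (1.95, 3.86-fold, adjusted p = 1.33e-05), Sesn2 (1.76) and Ddit4 (1.49) were among the rises. Of the 21 cell cycle inhibitor and senescence genes 6 fell, or 8 adjusted over the list alone, and 5 rose, Cdkn1a, Cdkn1b (0.99), Cdkn2a (0.82), Cdkn2b (1.76) and Rb1 (0.47), and the list did not pass (median -0.21, centred -0.09, camera adjusted p = 0.443). Lmnb1 and Hmgb2, whose loss often accompanies senescence, fell by 2.98 and 1.99. Among apoptosis genes Bbc3 (1.52) and Bcl2l11 (0.99) rose (list median 0.16, centred 0.28, camera adjusted p = 0.0866). Fas, Cdkn1b, Cdkn2a and Rb1 are named here after their values were seen.

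Stress and lipid metabolism moved in opposite directions. Amino acid supply and the integrated stress response gained 14 of 20 genes and lost none (median 0.56, centred 0.68, camera adjusted p = 8.44e-07, adjusted p = 0.0484 with an estimated correlation), led by Nupr1, Ddit3 (3.37) and Trib3 (3.08). Cholesterol and fatty acid synthesis lost 16 of 23 genes, or 17 adjusted over the list alone (median -0.76, centred -0.64, camera adjusted p = 1.8e-07, adjusted p = 0.0274 with an estimated correlation), with Fads2 (17362595) at -2.43, Fads1 at -1.83 and Fasn at -1.57. Only Scd1 (0.50, named after its value was seen) rose in that list. Oxidative phosphorylation fell in 9 of 28 cases, or 12 adjusted over the list alone (median -0.30, centred -0.18, camera adjusted p = 0.00203, adjusted p = 0.313 with an estimated correlation). Glycolysis was not called (median -0.22, centred -0.11, camera adjusted p = 0.163), with a small fall of Hk2 (-0.53). The oxidative stress (median -0.26, centred -0.14, camera adjusted p = 0.326) and unfolded protein response lists (median -0.28, centred -0.16, camera adjusted p = 0.681) did not pass, while Sqstm1 rose by 2.30 and Sdf2l1 fell by 2.17.

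Interferon-stimulated genes fell in 15 of 24 cases (median -0.62, centred -0.50, camera adjusted p = 0.000599, adjusted p = 0.222 with an estimated correlation), with Oasl2 (17441037) at -2.58 (5.99-fold) and Cxcl10 at -2.51. Immediate-early genes rose in 8 of 22 cases while Fos (-0.59) and Egr3 (-0.55), named after their values were seen, fell, or 12 up and 4 down adjusted over the list alone (median 0.35, centred 0.47, camera adjusted p = 0.0139, adjusted p = 0.439 with an estimated correlation). Inhibitory and exhaustion genes rose in 11 of 25 cases while Lag3 (-0.39) and Btla (-1.26) fell, or 13 up and 5 down adjusted over the list alone (median 0.31, centred 0.43, camera adjusted p = 0.0483, adjusted p = 0.414 with an estimated correlation). Without day 4 replicate 1 the inhibitory list had an adjusted p of 0.0869, without either day 0 array 0.0593, without day 9 replicate 2 0.0582 and without either KU55933 array 0.0513. Without the dim filter it was 0.0577. Nt5e (1.71), Ctla4 (1.71, 3.28-fold, adjusted p = 0.00049), Vsir (1.58) and Havcr2 (1.23, 2.35-fold, adjusted p = 0.000848) rose and Pdcd1 did not change (0.03, adjusted p = 0.871). The cytotoxic list did not pass with camera (median 0.04, mean 0.31, centred 0.16, camera adjusted p = 0.135) but did with fry (adjusted p = 0.00101). Of its 23 genes 6 rose, Gzmf by 4.44, or 8 adjusted over the list alone, while Gzmb (-0.07, adjusted p = 0.784) and Prf1 (-0.04, adjusted p = 0.819) did not pass. Cytokines did not pass as a list (median -0.24, centred -0.13, camera adjusted p = 0.322) but Xcl1 (-1.89), Lta (-1.11), Ifng (-0.86) and Tnf (-0.82) fell. NK receptors (median 0.11, mean -0.01, centred 0.23, camera adjusted p = 0.78), NK transcription factors (median 0.17, mean -0.02, centred 0.29, camera adjusted p = 0.728), trafficking (-0.23, 0.276), TNF receptor family (0.33, 0.217) and IL-2 and STAT5 genes (0.20, 0.128) were not called. Cd27 (-1.05), Slamf6 (-1.34, a lower bound) and Ncr1 (-0.60) fell and Cd69 (1.70) rose.

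Myeloid markers fell between day 4 and day 9 together with the division genes. Macrophage genes fell in 16 of 18 cases (median -2.26, centred -2.14, camera adjusted p = 1.67e-09, adjusted p = 0.183 with an estimated correlation), Lyz2 by 4.14 and Ctss by 3.61. Neutrophil genes fell in 12 of 15 cases, or 14 adjusted over the list alone (median -1.57, centred -1.46, camera adjusted p = 6.3e-08, adjusted p = 0.0274 with an estimated correlation), S100a9 by 4.42, while Ctsg rose. B cell genes fell in 9 of 11 cases, or 11 adjusted over the list alone (median -1.87, centred -1.76, camera adjusted p = 8.44e-07, adjusted p = 0.148 with an estimated correlation). Megakaryocyte genes fell (median -0.88, centred -0.76, camera adjusted p = 0.0257, adjusted p = 0.313 with an estimated correlation), a call lost without either day 0 array (0.0552). Dendritic cell genes were not called (median -0.47, centred -0.35, camera adjusted p = 0.128). With an estimated correlation 7 of the 15 called lists held, namely G2/M, G1/S, ATM and ATR signalling, homologous recombination, cholesterol synthesis, the amino acid and stress response list and neutrophil genes, and fry called 29. Of the 122 named genes past the threshold 108 stayed past it whichever array was left out, and all kept their sign.

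A small set of genes differed between chronically activated cells with and without KU55933. Interferon-stimulated genes, glycolysis genes and cholesterol and fatty acid synthesis genes were higher with KU55933, while p53 targets were not called. Division genes were slightly higher, a call lost with an estimated correlation (adjusted p = 0.119 for G1/S and 0.186 for G2/M). Egln3 (17281084), an oxygen-sensing prolyl hydroxylase induced under hypoxia, rose by 2.90 ± 0.22 (7.44-fold, adjusted p = 0.00316). Usp18 (17462437), a deconjugase of ISG15, rose by 2.05 ± 0.15 (4.15-fold, adjusted p = 0.00316) and Oasl2 by 2.03 ± 0.16 (4.08-fold, adjusted p = 0.00316). Hk2 (17468018), the first enzyme of glycolysis, rose by 1.17 ± 0.11 (2.25-fold, adjusted p = 0.00715) and the fatty acid desaturase Fads2 by 1.80 ± 0.16 (3.49-fold, adjusted p = 0.0061). The integrin Itgam (17483577) fell by 1.44 ± 0.11 (2.72-fold, adjusted p = 0.00316). In all, 138 of 13998 genes (0.986%) changed, 105 upward and 33 downward, and 56 of them at least 2-fold, 37 upward and 19 downward. Without adjustment 1710 genes had a p below 0.05. Arrays did not overlap for 48.1% of genes, against 33.3% by chance. Centring shifted changes by -0.07 and called 92 genes, 58.7% upward against 76.1% as deposited, 86 of them in the same direction both ways. The count depended on single arrays, at 255 without either day 0 array, 24 without either day 4 array, 11 without day 9 replicate 1, 10 without day 9 replicate 2, 1 without KU55933 replicate 1 and 14 without KU55933 replicate 2.

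Interferon-stimulated genes had the most members past the threshold with KU55933. Of the 24 tested 11 rose (8 centred) and none fell, or 20 adjusted over the list alone (median 0.66, centred 0.59, camera adjusted p = 4.7e-26, adjusted p = 0.0229 with an estimated correlation). Rtp4 rose by 2.16 ± 0.16 (4.46-fold, adjusted p = 0.00316), Irf7 by 1.23 (adjusted p = 0.00939), Oas3 by 1.18, Irf9 by 1.05 and Rsad2 by 0.99. Ifi204 (2.84, 7.14-fold, adjusted p = 0.0061), an interferon-inducible gene with near relatives, was among the largest rises, whereas Gbp11 (-1.40, adjusted p = 0.0257) was among the largest falls. Irf7, Irf9, Oas3 and Rsad2 were picked from the called list members after the values were seen.

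**Figure D3:**
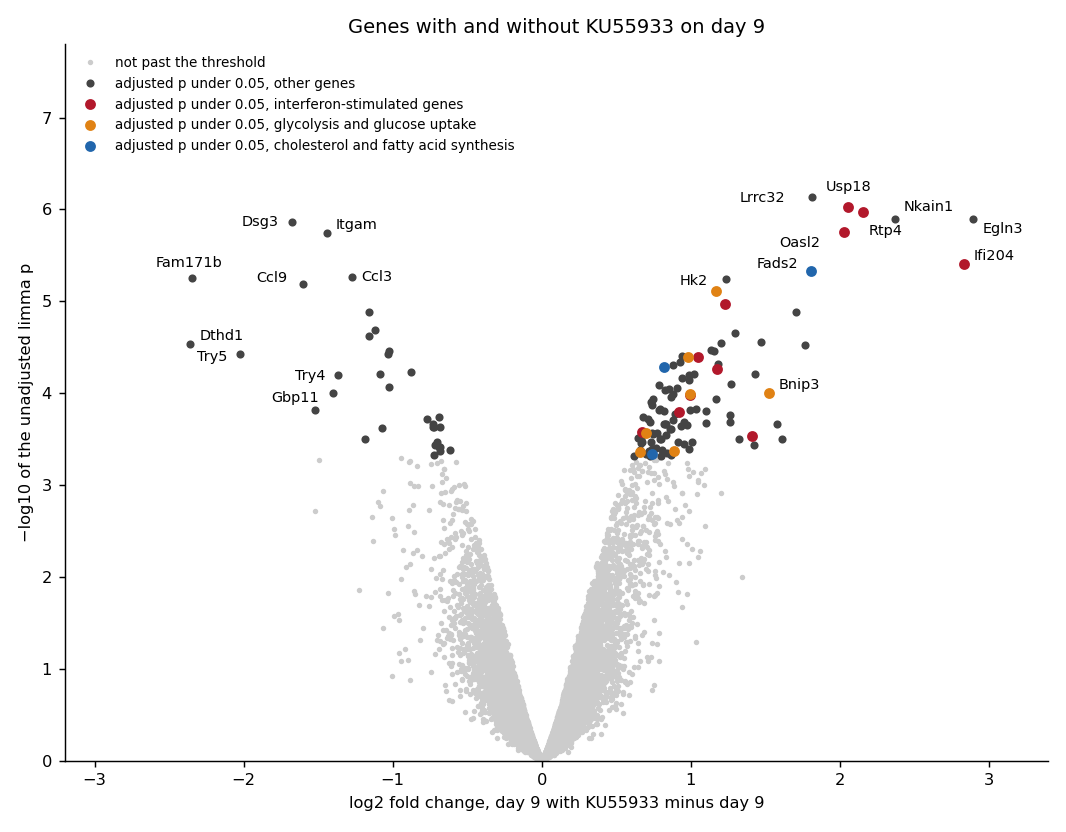
Day 9 with KU55933 against day 9, with the log2 fold change on the horizontal axis and minus log10 of limma's unadjusted p on the vertical axis; each point is 1 of the 13998 tested genes, and called genes of the interferon, glycolysis and cholesterol lists are coloured.

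Glycolysis rose with the inhibitor in 7 of 18 genes (4 centred), or 15 adjusted over the list alone (median 0.67, centred 0.60, camera adjusted p = 6.94e-19, adjusted p = 0.0209 with an estimated correlation). Bnip3 (1.53, 2.88-fold, adjusted p = 0.0257), Pfkl (0.99, adjusted p = 0.0257) and Pdk1 (0.98, adjusted p = 0.0172), several of them known hypoxia-responsive genes, were among them. Cholesterol and fatty acid synthesis rose in 3 of 23 genes (2 centred), or 16 adjusted over the list alone (median 0.46, centred 0.39, camera adjusted p = 2.22e-14, adjusted p = 0.0209 with an estimated correlation), with Fads2, Fads1 (0.82, adjusted p = 0.0197) and Lss (0.74, adjusted p = 0.0483) past the threshold. Amino acid supply and the integrated stress response was lower as a list (median -0.19, centred -0.26, camera adjusted p = 5.04e-06, adjusted p = 0.102 with an estimated correlation), with Nupr1 (-1.16, adjusted p = 0.016) and Ddit3 (-1.03, adjusted p = 0.0172), named after their values were seen, falling. Oxidative stress genes were higher as a list (median 0.20, centred 0.13, camera adjusted p = 0.0415, adjusted p = 0.554 with an estimated correlation) with none past the threshold alone, and this was lost without day 9 replicate 2 (0.142) or KU55933 replicate 2 (0.247). Oxidative phosphorylation (camera adjusted p = 0.548) and the unfolded protein response (camera adjusted p = 0.978) did not move as lists.

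Few division genes passed alone with KU55933. G1/S and replication genes past the threshold were Pole (0.94, adjusted p = 0.0172), E2f8 (1.02, adjusted p = 0.0199) and Mcm5 (0.86, adjusted p = 0.0365), 3 of 31 tested (2 centred), or 19 adjusted over the list alone (median 0.44, centred 0.37, camera adjusted p = 1.36e-12, adjusted p = 0.119 with an estimated correlation). For G2/M these were Top2a (0.79, adjusted p = 0.0239), Ccna2 (0.71, adjusted p = 0.0355) and Kif11 (0.68, adjusted p = 0.0344), 3 of 29 (1 centred), or 12 adjusted over the list alone (median 0.43, centred 0.36, camera adjusted p = 2.05e-09, adjusted p = 0.186 with an estimated correlation). Homologous recombination genes were higher as a list with none past the threshold alone (median 0.22, centred 0.15, camera adjusted p = 0.00231, adjusted p = 0.217 with an estimated correlation). No response of the p53 targets was detected, none of 28 passing even adjusted over the list alone. Their median of 0.02 became -0.05 on centring (camera adjusted p = 0.878), and with 2 arrays per group a small shift is not excluded. Neither Cdkn1a (0.23, adjusted p = 0.422) nor Mdm2 (-0.06, adjusted p = 0.923) passed. Of the ATM and ATR list only Timeless rose (0.90, adjusted p = 0.0335), a gene named after its value was seen and not called when centred, and neither Atm (17527054; -0.01, adjusted p = 0.989) nor Chek1 (0.44, adjusted p = 0.332) passed. That list had a median of 0.00 (camera adjusted p = 0.185). End joining (median -0.13, mean 0.02, centred -0.20, camera adjusted p = 0.978), base repair (camera adjusted p = 0.704), cell cycle inhibitors (0.978) and apoptosis genes (0.324) were not called.

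Lists of immune function genes shifted little with KU55933, though the single genes Itgam, Ccl3 and Ccl4 fell and Zbtb32 rose more than 2-fold. Il2ra rose by 0.67 (adjusted p = 0.0421, not called when centred) within an IL-2 and STAT5 list that was higher as a whole (median 0.18, centred 0.11, camera adjusted p = 0.00345, adjusted p = 0.205 with an estimated correlation). NK receptors were slightly lower as a list (median -0.12, centred -0.19, camera adjusted p = 0.00138, adjusted p = 0.552 with an estimated correlation), with 2 of 30 past the threshold, Itgam down and Slamf7 (0.66, adjusted p = 0.041) up, the latter not called when centred, or 3 down and 1 up adjusted over the list alone. The chemokines Ccl3 (-1.27, adjusted p = 0.0061), Ccl4 (-1.16, adjusted p = 0.0103) and Ccl9 (-1.60, adjusted p = 0.00647) fell and Zbtb32 (1.2, adjusted p = 0.0166) and Ccr7 (0.83, adjusted p = 0.0356) rose. Gzmb (-0.05, adjusted p = 0.935), Prf1 (0.25, adjusted p = 0.411), Havcr2 (-0.05, adjusted p = 0.931) and Ctla4 (0.89, adjusted p = 0.0957) did not pass. Cytotoxic (camera adjusted p = 0.641), cytokine (0.548), inhibitory (0.149), trafficking (0.521), TNF receptor family (0.4), NK transcription factor (0.276) and immediate-early lists (0.623) were not called. Macrophage genes were slightly lower (median -0.21, centred -0.28, camera adjusted p = 0.0329, adjusted p = 0.664 with an estimated correlation), a result lost without day 9 replicate 2 (0.142) or KU55933 replicate 1 (0.157), without the dim filter (0.0868) and after quantile normalization (0.0646). Neutrophil (0.521), B cell (0.978), dendritic cell (0.247) and T cell genes (0.084) were not called. Slamf7, Ccl3, Ccl4, Zbtb32 and Ccr7 are named after their values were seen. With an estimated correlation 3 of the 11 called lists held, those of interferon-stimulated genes, glycolysis and cholesterol synthesis, and fry called 9, leaving out NK receptors (0.107), the oxidative stress response (0.11) and macrophage genes (0.421). Of 29 named genes past the threshold only Nkain1 stayed past it whichever array was left out, and all 29 kept their sign.

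Cells kept with KU55933 still differed widely from day 4 cells. Division and recombination genes were low and p53 targets high, much as on day 9 without inhibitor, but glycolysis genes stood above day 4. With an estimated correlation the division and recombination calls held and those of p53 targets (adjusted p = 0.0579) and glycolysis (adjusted p = 0.0703) were lost. Bub1 fell by 4.07 (16.7-fold) and Mki67 by 3.20, Cdkn1a rose by 1.68 (3.20-fold, adjusted p = 2.32e-05) and Mdm2 by 1.45, and Bnip3 rose by 1.96 (3.9-fold, adjusted p = 0.000387). The largest rises were B4galnt2 (4.69, 25.9-fold, adjusted p = 2.38e-06), Il23a (4.48, 22.4-fold) and Ctsg (4.44), and the largest falls Chil3 (-5.08, 33.9-fold), Cybb (-5.04) and Lyz2 (-4.82). In all, 3640 of 13998 genes (26.0%) changed, 1719 upward and 1921 downward, 1162 of them at least 2-fold. The count was 1984 without day 4 replicate 1, 2053 without day 4 replicate 2, 2116 without KU55933 replicate 1 and 2157 without KU55933 replicate 2. Arrays did not overlap for 67.1% of genes, against 33.3% by chance, and centring (shift 0.05) called 3782 genes, 3483 in the same direction both ways.

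Every G2/M gene (29, median -3.2, centred -3.16, camera adjusted p = 2.58e-33, adjusted p = 0.0318 with an estimated correlation) and every G1/S gene (31, median -2.04, centred -1.99, camera adjusted p = 8.94e-26, adjusted p = 0.0318 with an estimated correlation) was lower than on day 4. Homologous recombination genes fell in 18 of 23 cases, or 19 adjusted over the list alone (median -1.64, centred -1.59, camera adjusted p = 8.51e-12), and ATM and ATR genes in 18 of 27, or 19 adjusted over the list alone (median -0.71, centred -0.67, camera adjusted p = 1.32e-09). Neutrophil genes fell in 12 of 15 (median -1.80, centred -1.76, camera adjusted p = 1.96e-07), or 13 adjusted over the list alone, and these 5 lists were the ones that held with an estimated correlation. Targets of p53 rose in 14 of 28 cases, or 16 adjusted over the list alone (median 0.48, centred 0.52, camera adjusted p = 2.06e-05, adjusted p = 0.0579 with an estimated correlation), including Trp53inp1 (1.85) and Ddit4 (1.81). Glycolysis rose in 11 of 18 (median 0.48, centred 0.52, camera adjusted p = 0.000333, adjusted p = 0.0703 with an estimated correlation), with Slc2a1 at 1.04 and Slc2a3 at 0.90. Amino acid supply and the stress response rose in 11 of 20, or 13 with 3 falling adjusted over the list alone (median 0.57, centred 0.62, camera adjusted p = 0.000166, adjusted p = 0.0939 with an estimated correlation). Cholesterol and fatty acid synthesis fell in 10 of 23, or 12 adjusted over the list alone (median -0.36, centred -0.31, camera adjusted p = 0.0111, adjusted p = 0.116 with an estimated correlation).

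Interferon-stimulated genes were higher with the inhibitor than on day 4 in 9 of 24 cases and lower in 6, or 11 and 6 adjusted over the list alone (median 0.43, centred 0.47, camera adjusted p = 0.0249, adjusted p = 0.357 with an estimated correlation), with Irf9 (1.23), Rsad2 (1.13) and Isg15 (1.11) up and Cxcl10 (-1.87) down. The call was lost without day 4 replicate 1 (0.0604). IL-2 and STAT5 genes rose in 10 of 20 (median 0.47, centred 0.52, camera adjusted p = 0.0013, adjusted p = 0.116 with an estimated correlation) and immediate-early genes in 11 of 22, or 13 adjusted over the list alone (median 0.42, centred 0.47, camera adjusted p = 0.00418, adjusted p = 0.371 with an estimated correlation). Apoptosis genes rose in 6 of 22 (median 0.21, centred 0.25, camera adjusted p = 0.0249, adjusted p = 0.357 with an estimated correlation), a call lost without KU55933 replicate 2 (0.0752), and oxidative phosphorylation fell in 8 of 28, or 11 adjusted over the list alone (median -0.28, centred -0.23, camera adjusted p = 0.00424, adjusted p = 0.321 with an estimated correlation). Macrophage (16 of 18 fell, median -2.47, centred -2.42, camera adjusted p = 3.84e-11, adjusted p = 0.116 with an estimated correlation) and B cell genes (8 of 11 fell, or 9 adjusted over the list alone, median -1.86, centred -1.81, camera adjusted p = 4.86e-07, adjusted p = 0.116 with an estimated correlation) fell. Dendritic cell (median -0.63, centred -0.58, camera adjusted p = 0.00814, adjusted p = 0.116 with an estimated correlation) and megakaryocyte genes (median -0.66, centred -0.61, camera adjusted p = 0.0187, adjusted p = 0.317 with an estimated correlation) fell as lists. Ctla4 rose by 2.61 (6.09-fold, adjusted p = 5.71e-05), Lag3 (-0.70) and Xcl1 (-2.12) fell and Tigit did not pass (0.23, adjusted p = 0.637). NK receptors were not called (median 0.03, mean -0.16, centred 0.08, camera adjusted p = 0.499). Camera called 18 lists and fry 28. Of 121 named genes past the threshold 112 stayed past it whichever array was left out.

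Many genes that differed with the inhibitor had changed in the opposite direction between day 4 and day 9. Among genes called in both the day 9 against day 4 and the KU55933 comparisons, 55 had fallen and were higher with the inhibitor, where 16.4 would fall together if the calls were independent, and 24 had risen and were lower with it (4.03 if independent). Another 16 had risen and rose further (12.8 if independent) and 3 had fallen and fell further (5.16 if independent). The day 9 arrays enter both comparisons, so part of the excess can come from noise they share. In 100 simulated data sets all groups had the same mean, so neither day nor inhibitor had an effect. No gene was called in both comparisons there, which that setting makes likely in advance. The simulations therefore do not say how large that part of the counts is. The covariance of the 2 sets of changes across genes was -0.0607. In 100 data sets simulated in the same way it was -0.0150 (-0.0159 to -0.0141), a difference of -0.0457. The simulated noise was independent between genes, so that range does not measure the spread between arrays. The difference was not tested, and the closing section gives it with single arrays left out. The correlation across genes, which are not independent replicates, was -0.331. It cannot be set against the simulated -0.499, because the simulations hold no change between day 4 and day 9 and such change alters a correlation.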

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

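In this part the test against the NK receptor list, the test of myeloid and dendritic cell markers and the test of cycling myeloid cells were chosen after the results were seen. The set of p53 targets taken as also induced by ATF4 or CHOP was likewise not among the lists written before the data were examined.

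Target genes of p53 were higher on day 9 than on day 4, a call just lost with an estimated correlation (adjusted p = 0.0513). The 5 members taken here as also induced by ATF4 or CHOP could have carried the rise. Without them the 23 remaining genes had a median of 0.43 (camera p = 0.0021, p = 0.0488 with an estimated correlation, both unadjusted). That argues against these 5 alone. Any other member that ATF4 or CHOP induces stayed in, so the test cannot exclude a part of the integrated stress response. Scaling of the arrays after the fall of division genes could also raise a list, but its median of 0.53 for 28 genes stood at percentile 100 of 10000 random lists matched on expression (middle range -0.23 to 0.17), which argues against it. Loss of other cell types stays open. The p53 median exceeded that of the 30 NK receptors (0.11) by 0.42, with a bootstrap interval from -0.12 to 1.03. That interval resamples genes and does not measure the spread between arrays.

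Interferon-stimulated genes were higher with KU55933. More myeloid or dendritic cells in those cultures could have carried the rise, but their 29 markers had a median of -0.20 (bootstrap interval over genes -0.35 to 0.04). The lower end of such an interval for the 24 interferon-stimulated genes was 0.47. For these markers the values argue against more of those cells, but intervals over genes do not measure the spread between arrays. A single aberrant day 9 array is also unlikely to be the source, because the median rise was 0.67 against one day 9 array and 0.68 against the other.

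Division genes rose by day 4 and were low again by day 9. The G1/S list had medians of 2.33 (day 4 against day 0), -0.22 (day 9 against day 0) and -2.31 (day 9 against day 4), and the G2/M list 3.12, -0.46 and -3.51; against day 0 no call held with an estimated correlation (adjusted p = 0.0935 on day 4 and 0.375 on day 9 for G1/S, 0.0852 and 0.262 for G2/M), and that of G1/S on day 9 was lost without day 0 replicate 2 (0.0986). Loss of cycling myeloid cells may have contributed and cannot be told apart from arrest of the NK cells, because on day 4 macrophage markers stood at -0.27 but neutrophil markers at 1.75. In the whole set 176 genes were higher on day 4 and lower on day 9 than on day 0, and 80 were lower on day 4 and higher on day 9.

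Transcript clusters with no gene listed were outside the gene tests, and 3131 of 7626 bright ones differed between day 4 and day 0 (41.1%, 1274 higher and 1857 lower), against 1 between KU55933 and day 9.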

How the results depend on the processing

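The removal of the day 0 arrays from the fits for day 9, KU55933 and day 4 was chosen after the results were seen; all other settings were chosen before.

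With 2 arrays per group the count for KU55933 against day 9 was the least stable result (138 genes as reported). It was 49 without a dim filter, 256 with the filter at percentile 75, 16 with every cluster tested, 83 after quantile normalization, 320 with a mean-variance trend, 333 with array weights, 38 with only the 4 arrays compared, 56 with adjusted p and a 2-fold minimum, 80 with unadjusted p and a 2-fold minimum, 26 with treat and 255 without the day 0 arrays. Leaving out single arrays gave 1 to 255. Day 0 arrays had the largest replicate spread (array weights 0.395 on day 0, 1.63 on day 4, 1.19 on day 9 and 1.31 with KU55933), so giving them less weight or none lowers the shared variance by construction; for the other changes the cause was not tested. The mean of clusters (130), centring (92) and robust fitting (127) stayed closer.

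With replicate number as a block, which assumes a pairing that the labels do not state, KU55933 against day 9 gave 60 genes, and the other comparisons gave 8311, 8056, 3635 and 3441. The call of the inhibitory list for day 9 against day 4 was lost with the block (adjusted p = 0.0711). Deviations from the group mean correlated between -0.033 and 0.053 across groups, so the numbers gave no sign of pairing.

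For the other comparisons, the 2-fold minimum gave 4045 genes for day 4 against day 0, 3843 for day 9 against day 0, 1240 for day 9 against day 4 and 1162 for KU55933 against day 4; with unadjusted p these were 4046, 3847, 1251 and 1166. Treat gave 2128 for day 9 against day 4 and 1929 for KU55933 against day 4. Leaving out single arrays gave 6669 to 8657, 6893 to 8449, 2223 to 4933 and 1984 to 4693.

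The authors' averages come from these same arrays, lie within 0.005 of the means used here and hold only the genes they list. Medians taken from them differ through the genes left out, so kept signs are no independent check. They moved 10 list medians without changing a sign. These were 1.53 for cytotoxic genes (day 4 against day 0); -1.03 for trafficking, 1.155 for IL-2 and STAT5, 0.86 for oxidative phosphorylation and -2.805 for dendritic cell genes (day 9 against day 0). For day 9 against day 4 they were -1.18 for ATM and ATR signalling, -1.975 for homologous recombination, -0.765 for interferon-stimulated and -1.75 for neutrophil genes, and for KU55933 against day 4 -1.18 for ATM and ATR signalling.

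Lists called numbered 16, 16, 15, 11 and 18 with camera's preset correlation in the order of the report, 0, 0, 7, 3 and 5 with an estimated correlation and 31, 33, 29, 9 and 28 with fry. The excess covariance of the KU55933 and day 9 changes (-0.0457) was -0.0355 without a dim filter, -0.0618 at percentile 75 and between -0.0631 and -0.0316 with single arrays left out.

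Among the named genes, signs reversed only for those that had not passed the threshold. Over all genes, centring changed the sign for 78 called genes of day 4 against day 0, as given above. For day 4 against day 0 Atm was -0.38 after quantile normalization and -0.058 to 0.16 with single arrays left out (-0.058 without day 0 replicate 1, -0.015 without day 4 replicate 1). For day 9 against day 4 the lone reversal came without day 4 replicate 1, at 0.033 for Gzmb (range -0.18 to 0.033), -0.014 for Pdcd1 (-0.014 to 0.073) and -0.00465 for Il2ra (-0.00465 to 0.15). For KU55933 against day 9 Gzmb was 0.077 after quantile normalization, Chek2 ran from -0.39 to 0.069 (highest without day 9 replicate 2), and without KU55933 replicate 1 Atm was 0.18 (-0.20 to 0.18), Ifng 0.091 (-0.39 to 0.091) and Havcr2 0.00205 (-0.11 to 0.00205). For KU55933 against day 4 Eomes was -0.00093 without KU55933 replicate 1 and 0.019 without replicate 2.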

Other observations

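The HIF gene list and the desmosome gene tests of this part were chosen after the results were seen.

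Several desmosome and cadherin genes were higher in chronically activated than in fresh cells. Besides Dsc2, Dsg2 rose by 4.72, Dsg3 by 2.61 and Cdh1 by 1.42 between day 0 and day 9. Dsg2, Dsg3 and Dsc1 lay below the array median on day 0, so their rises are lower bounds. A second transcript cluster of Dsg2 stayed below the median, at 2.99 on day 0 and 3.07 on day 9. Of 10 other desmosome and cadherin junction genes 7 were higher on day 9, Dsc1 (0.75), Dsp (1.23), Pkp2 (2.58), Pkp3 (0.63), Pkp4 (1.21), Ctnna1 (1.32) and Ctnnb1 (0.80), against 36.0% of all tested genes; Ctnnd1 (-1.51) and Cdh3 (-0.52) were lower and Jup was level (-0.02). Among the cadherin cluster's 6 other measured genes the largest measured rise was 0.75 (Dsc1), itself a lower bound. Dsc3 (0.19), Dsg1a (-0.36), Dsg1b (-0.24), Dsg1c (-0.55) and Dsg4 (-0.13) did not pass the dim filter. These values give no sign that the whole cluster was activated, but probes near the floor cannot exclude it. Against day 4, only 3 of these 10 genes were called higher on day 9, Dsc1 (0.82), Dsp (1.05) and Pkp3 (0.66). None was called lower, and Pkp2 (0.62), Pkp4 (0.27), Ctnna1 (0.01) and Ctnnb1 (0.16) did not pass. No list test of the junction genes was made. Whether the adherence used to collect the cells plays a part could be asked with cells collected in suspension; the 7 genes alone do not say.

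Target genes of HIF also moved. Of 28 HIF target genes outside the glycolysis list 20 rose between day 0 and day 9, against 36.0% of all tested genes. The largest rises were Ero1a (4.66) and Plod2 (3.43), and Ppfia4 (-1.04), Adm (-0.98), Pfkfb4 (-0.94) and Mxi1 (-0.68) fell. From day 4 to day 9, 13 of the 28 rose and none fell, against 12.2% of all tested genes rising. No list test was made for these days. With KU55933 the same 28 genes shifted up by a median of 0.31 (camera p = 4.63e-09, p = 0.00496 with an estimated correlation), and 2 of them passed alone, P4ha1 (0.73) and Mxi1 (0.82). That is consistent with a broader rise of HIF targets alongside Egln3, Bnip3, Pdk1 and Hk2, and protein levels of HIF were not measured.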
